A study of Arabidopsis thaliana with 15 samples.

How the data were processed

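Roots of Arabidopsis thaliana Columbia-0 plants were measured on Affymetrix ATH1 arrays with biotin-labelled amplified RNA, in 15 samples of 5 groups with 3 biological replicates each. Roots of at least 5 plants were pooled per sample. The groups were roots before nitrogen supply, after 26 h without nitrogen, and roots 1.5 h and 8 h after supply of 1 mM nitrate or 1 mM ammonium.

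The deposited values were RMA expression values per probe set on a log2 scale. Per the submitters' processing notes RMA and limma were used, with no version, role or design stated. The log2 scale was read from the values, which lay between 2.45 and 13.96. The medians were 6.781, 6.831 and 6.807 before supply, 6.776, 6.833 and 6.804 at 1.5 h of nitrate, 6.762, 6.771 and 6.811 at 1.5 h of ammonium, 6.762, 6.785 and 6.806 at 8 h of nitrate, and 6.792, 6.815 and 6.831 at 8 h of ammonium. No scan files were used here, so the background correction was not checked.

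Values were used as deposited, without a filter, for all 22746 probe sets, of which 0 were array controls. A table of the array's deposited annotation named 1 gene for 13513 probe sets, several genes for 503 and none for 8730. Symbols came from a table of RefSeq genes (assembly TAIR10.1), which matched 13436 of the probe sets with 1 gene. A gene with several probe sets (152 genes) was represented by the one with the highest mean over all samples. Genes without a symbol there were named by locus or by the symbol of a fixed list (HHO1, HHO2, HHO3, PGD1, PGD3 and NRT1.4).

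Each probe set was fitted with limma 3.58.1 in R 4.3.3, with 5 group means over all 15 samples, and 9 contrasts were tested with moderated statistics (two-sided, prior degrees of freedom 5.11, residual degrees of freedom 10). The median residual standard deviation was 0.115 log2. P values were adjusted by the Benjamini-Hochberg method within each contrast and called below 0.05. The 9 contrasts were each supplied group against the roots before supply, nitrate against ammonium at each time, 8 h against 1.5 h within each ion, and the change of the ion difference with time. Figures were drawn in Python 3.11.15.

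The comparisons, tests, most alternatives, 28 gene lists and the rule for naming genes were fixed before the data were examined. The rule took, among probe sets with 1 named gene, the 6 largest rises and 6 largest falls in each of the 6 main comparisons (3 and 3 in the others) among called genes whose replicates did not overlap between groups. It further took up to 3 called members of each list with the smallest adjusted p, or the member with the smallest p where none was called. A set of 17 key genes was to be given whatever their result, of which 1, HHO1, had a named probe set and 16 had none in the tables used here. The criterion of no overlap was not applied to the change of the ion difference, which compares 4 groups. Up to 2 rising and 2 falling probe sets without a listed gene were also given for the main comparisons. Genes of the overlap and of the calls that differed between the ions were given as examples among those so named.

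Of 385 entries in the 28 fixed lists 42 had a named probe set, 9 lists had no member, and the 4 lists with at least 3 members were tested. A further 20 lists were written after the probe table showed which genes were named and before any expression value of a gene was seen, and the rule for naming list members was applied to them too. Lists were tested with limma's fry, which asks whether members move on balance in one direction, and with its mixed form, which asks whether they change in either direction. Neither compares a list with other genes. P values of lists were adjusted over lists and 7 comparisons, separately for fixed and added lists. Camera, which compares a list with the other genes, was run with the correlation between genes estimated per list. A value given with an estimated correlation is camera's. Camera answers another question than fry, so a call that camera lacks is not thereby traced to correlation.

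The overlap of the responses to the ions was set beside independent lists of the same sizes and beside 20 simulations of unchanged groups that shared the controls. A call against the roots before supply was also counted where the direct comparison of the ions was called in the matching direction, which includes genes that respond to both ions by different amounts.

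The procedure was tested on simulated data with the sizes of this design. Changes of 0.5, 1 and 2 log2 were recovered in 68.7%, 98.5% and 100% of the altered genes. Of 191 calls, 13 (6.81%) were false. All 5 lists moved by 0.5 log2 and 0 of 20 unmoved lists were called. The simulated noise was independent between genes, few genes were altered, and all members of a moved list moved alike. Members of real lists can be correlated and change in part, so this result does not carry over to the list calls here.

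Alternatives were a second quantile normalization, centring of samples on their medians, removal of dim probe sets (mean under 5 log2, which left 15739), variance with a trend and robust estimation, array weights, the replicate number as a block, only probe sets with 1 gene, only the groups compared, camera, and each replicate left out in turn. A pair of others was added after the data were seen: leaving out replicate 1 of the roots before supply in every comparison, and the mean deviation of the core hypoxia genes as a covariate.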

Results

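Transcript levels in roots of Arabidopsis thaliana, a small plant of the mustard family, were compared between roots supplied with nitrate and roots supplied with ammonium. Plants of the Columbia-0 accession were grown in hydroponic culture to growth stage 5.10 and kept without nitrogen for 26 h. They then received 1 mM nitrate or 1 mM ammonium. Roots were harvested just before supply and at 1.5 h and 8 h after it, which gave 5 groups of 3 biological replicates (15 samples, each pooled from at least 5 plants). Each sample was hybridised to an Affymetrix ATH1 array, and 22746 probe sets were measured. The number of arrays per group limits the precision, with a median standard error of 0.0921 log2 for a difference between 2 groups. Replicates of a group correlated at r = 0.9935 to 0.9978 across probe sets, and their differences had a standard deviation of 0.16 to 0.273 log2. The first 3 principal components held 32.3%, 19.7% and 16% of the variance.

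Changes are given as log2 ± the standard error of limma's fit (n = 3 per group), and a gene is said to rise or fall where limma's adjusted p was below 0.05. Between 2 groups, each gene named for its large change also had no overlap between the 3 values of one group and the 3 of the other, which chance alone gives to 10% of genes. Genes named for a large rise or fall were picked by the size of the RMA change among genes so called, without such overlap, of the 13513 probe sets with 1 named gene. The deposited values carried no detection call. HHO1 before supply and with ammonium lay below the lower quartile of each sample (4.36 to 4.52 log2) and was not shown to be above background, so its changes are differences of RMA levels and no fold is given for it. The same holds for the other genes named for large changes that had a group mean under 5 log2 on their lower side, which were AT2G30670, AT3G46880, PDF2.1, COR27, AT5G62360, AT2G22200, AT1G17615, OCT1, AT2G40250, AT2G33710 and AT4G27654. The order of such changes against others is not settled. The counter-ions of the nitrate and ammonium supplies were not stated, so each difference between the supplies includes any difference in counter-ion. No root without nitrogen was harvested at 1.5 h or 8 h, so each change against the roots before supply includes time since that harvest and time of day.

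**Figure D1:**
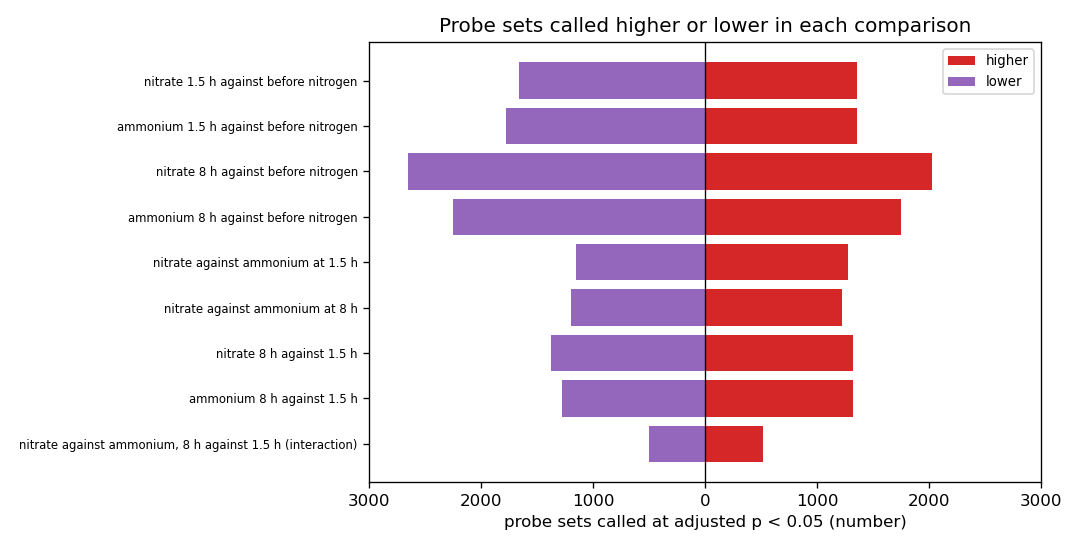
Number of probe sets higher (red, to the right) and lower (purple, to the left) in each of 9 comparisons, among 22746 tested with limma at an adjusted p below 0.05. The counts range from 1023 for the change of the ion difference with time to 4689 for nitrate at 8 h against the roots before supply.

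The comparison of roots at 1.5 h of nitrate with roots before supply addressed the early response to nitrate. Large rises among named genes were those of AT2G48080, by 5.81 ± 0.09 log2 (56-fold), and of HHO1 (AT3G25790), by 5.50 ± 0.10 log2. HHO1 encodes a GARP-family transcription factor, and its level went from 3.82 ± 0.14 (SD, n = 3) to 9.32 ± 0.10 on the log2 scale, the first of these not shown to be above background. Further rises were those of AT5G10210 by 4.34 ± 0.20, AT2G30670 by 4.05 ± 0.27, AT1G80380, which encodes the photorespiratory enzyme glycerate kinase, by 3.98 ± 0.11, and AT5G62720 by 3.13 ± 0.14. Large falls among named genes were those of AT1G64590 (−2.37 ± 0.15), the organic cation transporter OCT1 (−2.35 ± 0.22), SUFE2 (−2.29 ± 0.18), AT2G33710 (−2.20 ± 0.17), AT2G40250 (−2.19 ± 0.12) and AT5G45650 (−1.90 ± 0.11). Limma's adjusted p was 1.8e-15 for AT2G48080 and no higher than 1.3e-06 for any other gene of these 12.

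Among groups of genes, 3 of the 4 measured nitrate response regulators rose and none fell with nitrate at 1.5 h. They were HHO1 and its relatives HHO3 (AT1G25550, 2.21 ± 0.12) and HHO2 (AT1G68670, 1.13 ± 0.10). The list also counted 3 called members when adjusted over the list alone, and it shifted upward (fry, adjusted p = 3.2e-12). Camera, which compares a list with the other genes under an estimated correlation, gave an adjusted p of 0.0037. Values given below with an estimated correlation are from camera too. Both measured members of the list for nitrate assimilation and reductant supply rose, in either adjustment (2 called when adjusted over the list alone). They were PGD3 (AT5G41670, 2.34 ± 0.07) and PGD1 (AT1G64190, 1.52 ± 0.06), which encode 6-phosphogluconate dehydrogenases of the oxidative pentose phosphate pathway. A later list of 11 measured loci known from the field to be induced by nitrate had all 11 higher (median 2.34, adjusted p = 3.7e-12, and adjusted p = 0.001 with an estimated correlation). It holds 3 of the nitrate response regulators and both PGD genes, and since its genes were chosen as known to rise it is no independent evidence of direction. Of 14 genes of the tricarboxylic acid cycle and citrate use, 3 rose and 1 fell. The risers were SDH1-2, a succinate dehydrogenase subunit (0.77 ± 0.08), and the isocitrate dehydrogenase subunits IDH-VI (0.56 ± 0.06) and IDH-V (0.32 ± 0.07). This list had an upward shift (fry, adjusted p = 0.0047), and camera did not call it (adjusted p = 0.48). Its median was 0.0132 and 10 of the 14 genes were not called, so the shift rested on a few members. Of 14 glutathione S-transferases, 5 fell and 1 rose (adjusted p = 0.00057 downward, and adjusted p = 0.59 with an estimated correlation), with GSTU22 (−1.29 ± 0.11), GSTU20 (−0.58 ± 0.10) and GSTU23 (−0.53 ± 0.09) among the falls. The median of these 14 genes was −0.0579, against −0.0424 for all probe sets. Of 17 CC-type glutaredoxins, small redox proteins, 2 rose and 3 fell, with AT3G62930 at 2.71 ± 0.17 and AT4G33040 at −1.85 ± 0.11 (adjusted p = 0.95 for a shift in one direction, and 1.6e-13 for change in either direction, which 110 of the 140 tests of added lists passed). XTH16, a cell wall enzyme, fell by 1.36 ± 0.08, and the iron deficiency regulator BHLH101 was at −0.69 ± 0.12, called as well, while the dehydrin gene COR47 rose by 0.93 ± 0.08. Each of these last 2 was the called member of 2 in its list, for iron deficiency and for abscisic acid, also when adjusted over the list alone (1 and 1). Of 27 core hypoxia genes, 7 rose and 1 fell with nitrate (median 0.633), and the list was not called (adjusted p = 0.18). AT3G10040, the 1 measured member of the fixed hypoxia list, rose by 2.16 ± 0.53 (adjusted p = 0.011, 1 also when adjusted over the list alone). That call was lost without replicate 3 of the roots before supply or nitrate replicate 2 (adjusted p = 0.056 and 0.068) and with a variance trend and robust estimation (0.05).

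In this comparison, 3017 of 22746 probe sets were called by limma (1358 higher, 1659 lower), of which 417 changed at least 2-fold (322 higher, 95 lower). With array weights, which gave replicate 3 of the roots before supply a weight of 7.64 and replicate 1 of them 0.252, 6061 were called. Among 8730 probe sets without a listed gene, 260624_at (5.29 ± 0.17) and 265475_at (3.91 ± 0.08) had the largest rises, and 254215_at (−4.11 ± 0.20) and 251472_at (−2.70 ± 0.09) the largest falls.

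Roots at 1.5 h of ammonium were compared with the same roots before supply for the early response to ammonium. Among named genes AT2G48080 again had a large rise, of 4.11 ± 0.09 log2 (17.3-fold). Others were those of AT5G10040 (3.71 ± 1.11), the calmodulin-like gene CML38 (3.60 ± 0.66, 12.2-fold), GAT1_2.1, a class I glutamine amidotransferase gene (3.46 ± 0.28, 11-fold), AT2G20670 (3.23 ± 0.11) and AT5G19120 (2.90 ± 0.16). Falls among named genes included those of AT2G43890 (−2.01 ± 0.16), AT1G22160 (−1.69 ± 0.09), AT2G43880 (−1.68 ± 0.10), AT2G41810 (−1.63 ± 0.17) and the CC-type glutaredoxins AT4G33040 (−1.62 ± 0.11) and AT5G11930 (−1.49 ± 0.10). HHO1 was at 3.82 ± 0.17 (SD, n = 3), not shown to be above background, with a change of 0.00 ± 0.10 log2 (limma, adjusted p = 0.99). A second probe set of GAT1_2.1 rose by 1.65 (adjusted p = 0.0017).

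The nitrate response regulators shifted upward with ammonium as well (adjusted p = 5.4e-08), with 2 of 4 members higher and 1 lower, and 3 called when adjusted over the list alone. Camera did not call this list (adjusted p = 0.067). HHO3 rose by 2.26 ± 0.12 and HHO2 by 1.36 ± 0.10. PGD3 (0.95 ± 0.07) and PGD1 (0.49 ± 0.06) rose, and both were also called when adjusted over the list alone (2 of 2). Of the 11 loci known to be induced by nitrate, 10 rose (median 0.952, adjusted p = 4.6e-09, and adjusted p = 0.0047 with an estimated correlation), among them PGM (1.31 ± 0.09). The fixed list for oxidative and mitochondrial stress shifted upward (adjusted p = 4.9e-05, and adjusted p = 0.049 with an estimated correlation). It held 1 called member of 5, the zinc finger gene STZ (1.93 ± 0.29), and 2 when adjusted over the list alone. STZ and CML38 were both members of the touch and handling list (2 of 2 higher, also when adjusted over the list alone). A list of mitochondrial dysfunction genes, which shares 3 members with the oxidative and mitochondrial stress list, had 2 of 7 higher. They were AT2G32020 (1.2 ± 0.17) and AT5G14730 (0.54 ± 0.11), and the adjusted p was 0.0023 in fry and 0.23 in camera. Of 18 genes of auxin homeostasis and signalling 4 rose (adjusted p = 7e-04, and adjusted p = 0.072 with an estimated correlation), with the auxin-conjugating enzyme gene GH3.1 at 0.68 ± 0.10 and LBD16, a lateral root regulator, at 0.41 ± 0.09. WRKY53 rose by 0.66 ± 0.11 (1 of 1 measured in the pathogen defence list, also when adjusted over the list alone). Of 27 core hypoxia genes, 14 rose and 1 fell, with AT1G33055 at 2.89 ± 0.49, AT3G10040 at 2.49 ± 0.53 and AT5G66985 at 1.49 ± 0.22. The hypoxia list had a median of 1.23 (adjusted p = 0.028, and adjusted p = 0.41 with an estimated correlation). UGT76B1 rose by 1.03 ± 0.09, and UGT72E2, which glucosylates monolignols, fell by 1.19 ± 0.07.

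Limma called 3139 probe sets here (1359 higher, 1780 lower, with 51.9% higher in place of 43.3% after samples were centred on their medians), of which 306 changed at least 2-fold (261 higher, 45 lower). The hypoxia genes lay above their 15-sample mean by 0.90, 0.12 and 0.72 log2 in the 3 ammonium samples and below it by −0.69, −0.61 and −0.99 in those before supply. With that deviation as a covariate 1149 were called, against 2069 with only these 6 samples in the fit and 6151 with array weights. The deviation comes from the same arrays and did not overlap between these groups, so as a covariate it also takes up group difference. The lower count therefore cannot show how many calls went with the hypoxia genes. The upward call of the hypoxia list was lost without replicate 2 or 3 of the roots before supply (adjusted p = 0.053 and 0.083) and without ammonium replicate 1 or 3 (adjusted p = 0.084 and 0.063), and that of AT5G10040 without replicate 1 or 3 of either group (adjusted p = 0.077, 0.13, 0.13 and 0.093) and with a variance trend and robust estimation (0.11). Among probe sets without a listed gene, 260030_at (3.99 ± 0.16) and 267045_at (3.96 ± 0.09) rose and 251472_at (−2.35 ± 0.09) and 255812_at (−1.64 ± 0.15) fell.

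**Figure D2:**
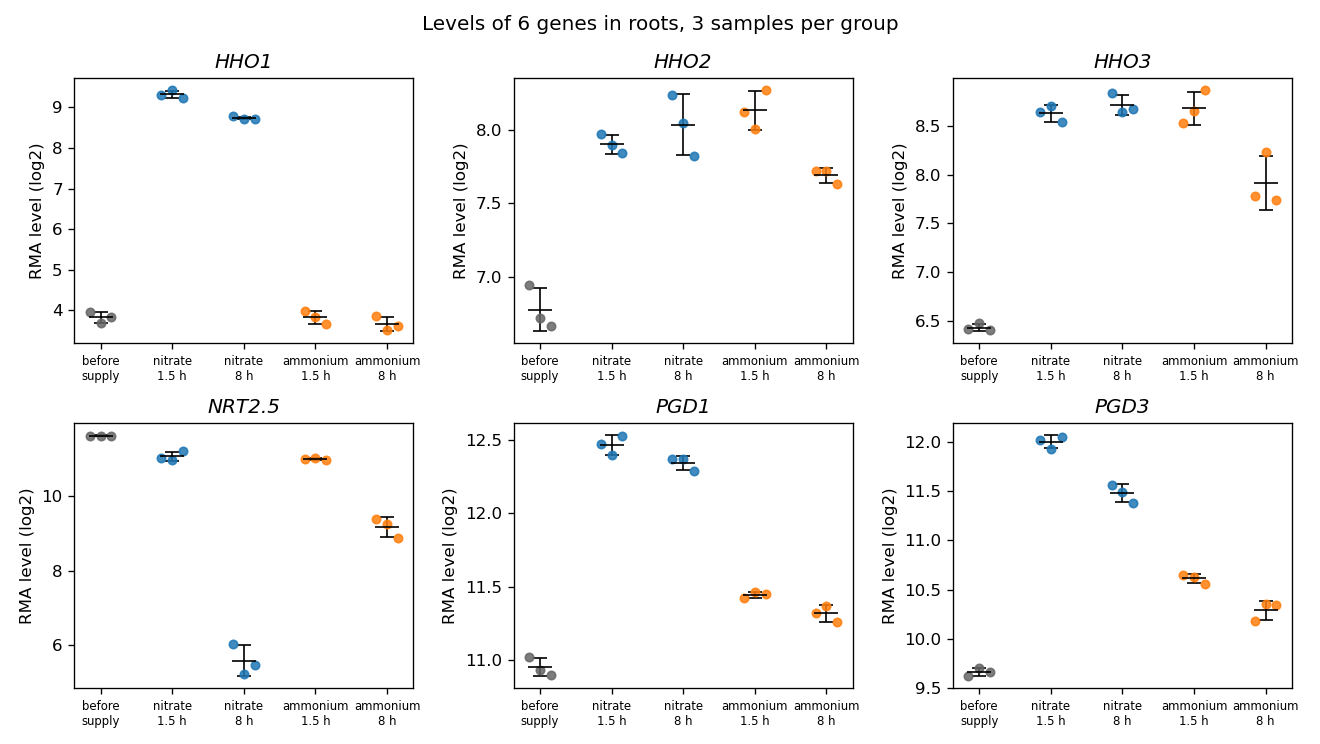
Deposited RMA level (log2, vertical axis, each plot on its own range) of 6 genes in the 5 groups, with 1 point per sample and black bars for the mean and its SD (n = 3). HHO1 stands at 9.32 and 8.74 on average with nitrate and at 3.82 and 3.66 with ammonium, against 3.82 before supply, while NRT2.5 goes from 11.62 before supply to 5.57 with nitrate and 9.18 with ammonium at 8 h.

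At 8 h of nitrate against the roots before supply, NRT2.5, a high-affinity nitrate transporter of nitrogen-starved roots, had a change of −6.05 ± 0.16 log2 (66.2-fold lower). Other large falls were those of AT5G04120 (−5.88 ± 0.49), OCT1 (−5.74 ± 0.22), AT1G64590 (−4.06 ± 0.15), AT1G22160 (−3.67 ± 0.09) and AT2G40250 (−3.09 ± 0.12). AT2G48080 (5.35 ± 0.09, 40.8-fold) and HHO1 (4.92 ± 0.10) again lay among the large rises of named genes, with AT5G10210 (5.02 ± 0.20), AT1G49500 (4.37 ± 0.12), AT4G39675 (4.29 ± 0.57) and AT3G46880 (4.21 ± 0.18). The highest adjusted p of these 12 in limma was 3.9e-05, for AT4G39675.

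The nitrate response regulators shifted upward at 8 h of nitrate (adjusted p = 3.2e-12, and adjusted p = 0.0061 with an estimated correlation), with 3 of 4 higher in either adjustment (3 when adjusted over the list alone), including HHO3 (2.3 ± 0.12) and HHO2 (1.26 ± 0.10). PGD3 rose by 1.81 ± 0.07 and PGD1 by 1.4 ± 0.06 (2 of 2 measured, also when adjusted over the list alone). Both measured members of the nitrate transport list fell, NRT2.5 and NRT1.4 (AT2G26690, −0.66 ± 0.14), and both were called when adjusted over the list alone (2 of 2). All 11 loci known to be induced by nitrate rose (median 2.3, adjusted p = 3.7e-12, and adjusted p = 0.0014 with an estimated correlation). Of the 14 tricarboxylic acid cycle and citrate genes, 4 rose and 2 fell (adjusted p = 3.6e-06 upward, and adjusted p = 0.28 with an estimated correlation), with SDH1-2 at 1.63 ± 0.08, IDH-VI at 0.91 ± 0.06 and ACLB-1, a subunit of ATP-citrate lyase, at −0.50 ± 0.06. Among 14 glutathione S-transferases 5 fell and none rose (adjusted p = 3.2e-07, and adjusted p = 0.17 with an estimated correlation), with GSTU22 at −2.22 ± 0.11 and GSTU23 at −1.53 ± 0.09. Core histone genes had 2 of 6 lower, HTB2 (−0.43 ± 0.09) and HTB1 (−0.41 ± 0.07), with a downward shift (adjusted p = 0.0019, and adjusted p = 0.47 with an estimated correlation). The glutaredoxin genes AT4G33040 (−2.88 ± 0.11) and AT5G11930 (−2.59 ± 0.10) fell and AT3G62930 rose by 2.35 ± 0.17, in a list of 17 with 5 higher and 2 lower (adjusted p = 0.13 downward, with a median of 0.0561 and a mean of −0.0775). SWEET14, a sugar transporter (−2.28 ± 0.18), BHLH101 (−1.01 ± 0.12) and the peroxidase gene AT5G15180 (−1.36 ± 0.09) fell, while ATG8H rose by 0.60 ± 0.08, as 1 of 7 in the autophagy list (1 when adjusted over the list alone, adjusted p = 0.062 for the list). Core hypoxia genes had 5 of 27 higher and 1 lower (median 0.0496), and the list was not called (fry, adjusted p = 0.62).

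In total 4689 probe sets were called by limma at 8 h of nitrate (2031 higher, 2658 lower), and 599 of them changed at least 2-fold (362 higher, 237 lower). Array weights gave 7177. Among probe sets without a listed gene, 266477_at (5.03 ± 0.19) and 260624_at (4.81 ± 0.17) rose and 254215_at (−4.74 ± 0.20) and 266719_at (−4.24 ± 0.13) fell.

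At 8 h of ammonium against the roots before supply, AT2G48080 (4.22 ± 0.09, 18.6-fold) and the defensin-family gene PDF2.1 (4.19 ± 0.17) had large rises among named genes. AT5G62360 (2.98 ± 0.23), GAT1_2.1 (2.84 ± 0.28), AT3G29970 (2.77 ± 0.75) and COR27, a gene regulated by cold and the circadian clock (2.65 ± 0.13), rose too. Large falls among named genes were those of AT5G04120 (−3.28 ± 0.49), AT2G40250 (−2.69 ± 0.12), AT5G15950 (−2.55 ± 0.12), NRT2.5 (−2.45 ± 0.16, 5.45-fold lower), AT1G22160 (−2.23 ± 0.09) and AT1G64590 (−2.14 ± 0.15). HHO1 had a change of −0.17 ± 0.10 (limma, adjusted p = 0.33). The other probe set of GAT1_2.1 rose by 1.24 (adjusted p = 0.0099).

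HHO3 (1.49 ± 0.12) and HHO2 (0.91 ± 0.10) were the 2 called members of 4 among the nitrate response regulators, which had 3 when adjusted over the list alone. That list shifted upward (fry, adjusted p = 3.4e-06), and camera did not call it (adjusted p = 0.23). PGD3 (0.63 ± 0.07) and PGD1 (0.37 ± 0.06) rose (2 of 2, also when adjusted over the list alone), while NRT2.5 and NRT1.4 (−0.91 ± 0.14) fell (2 of 2 in the nitrate transport list, also when adjusted over the list alone). Of the 11 loci known to be induced by nitrate, 9 rose (median 0.885, adjusted p = 3.1e-08, and adjusted p = 0.02 with an estimated correlation). Among NRT1/PTR family transporters 2 of 11 fell and none rose (adjusted p = 0.0028, and adjusted p = 0.4 with an estimated correlation), namely NRT1.4 and AT1G68570 (−0.44 ± 0.08). Among 28 genes of cell wall loosening 9 fell and 1 rose, with XTH16 at −0.81 ± 0.08 and EXPB3 at −0.75 ± 0.12 (adjusted p = 0.0023, and adjusted p = 0.38 with an estimated correlation, and 0.05 with only these 6 samples in the fit). Core hypoxia genes had 11 of 27 higher and 1 lower, among them PDC2, a pyruvate decarboxylase of fermentation (2.51 ± 0.41), and AT5G66985 (1.3 ± 0.22), but the list was not called (adjusted p = 0.056). AT3G10040 was at 1.38 ± 0.53 (adjusted p = 0.091, and 1 of 1 when adjusted over the list alone, which with 1 member is its unadjusted p). Of 14 SWEET sugar transporters 2 fell and 1 rose, with SWEET14 at −1.69 ± 0.18 and SWEET13 at −1.15 ± 0.13 (adjusted p = 0.012 downward, and adjusted p = 0.65 with an estimated correlation). That call was lost without replicate 3 of the roots before supply (adjusted p = 0.069). ATG8H rose by 0.53 ± 0.08, as 1 of 2 called in the autophagy list (4 when adjusted over the list alone, median −0.000589 and mean 0.154, adjusted p = 0.14 upward). GSTU23 fell by 1.46 ± 0.09 and GSTU22 rose by 0.63 ± 0.11.

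Limma called 4008 probe sets (1755 higher, 2253 lower), of which 380 changed at least 2-fold (259 higher, 121 lower). The hypoxia genes deviated by −0.17, 0.74 and 0.74 log2 in these 3 samples, again above all those before supply. As a covariate this deviation thus takes up group difference here too. With that deviation as a covariate 2083 were called, against 6631 with array weights, and the rise of AT3G29970 was lost without replicate 3 of the roots before supply or without ammonium replicate 2 or 3 (adjusted p = 0.056, 0.087 and 0.08), and with a variance trend and robust estimation (0.06). Among probe sets without a listed gene, 260795_at (4.42 ± 0.17) and 266477_at (4.40 ± 0.19) rose and 266719_at (−4.47 ± 0.13) and 261569_at (−4.41 ± 0.18) fell.

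**Figure D3:**
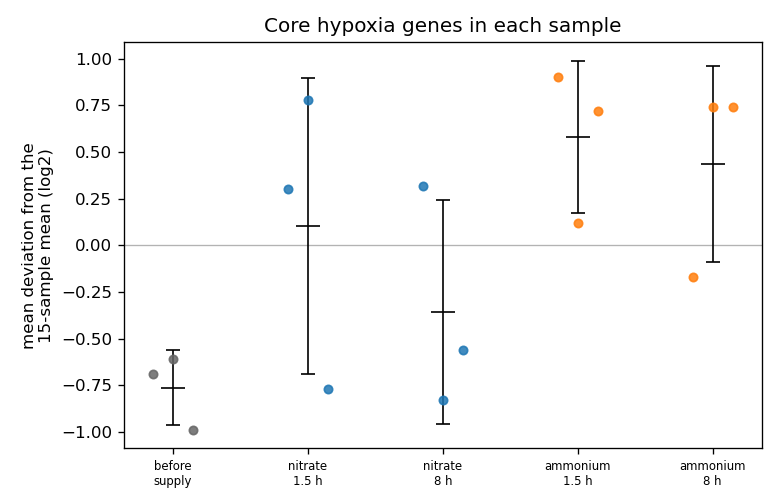
Mean deviation of 27 core hypoxia genes from their mean over all 15 samples (log2, vertical axis) in each sample of the 5 groups, with bars for the group mean and its SD (n = 3). The values range from −0.99 to −0.61 before supply, from −0.77 to 0.78 at 1.5 h of nitrate, from 0.12 to 0.90 at 1.5 h of ammonium, from −0.83 to 0.32 at 8 h of nitrate and from −0.17 to 0.74 at 8 h of ammonium.

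The direct comparison of nitrate with ammonium at 1.5 h addressed which transcripts differed between the 2 supplies at equal time after addition. The time of day of the harvests was not stated. Among named genes HHO1 was higher with nitrate by 5.50 ± 0.10 log2, against a level with ammonium that was not shown to be above background. AT2G22200 (2.71 ± 0.17), AT2G30670 (2.65 ± 0.27), AT5G62720 (2.62 ± 0.14), AT5G01740 (2.55 ± 0.13) and AT5G19700 (2.32 ± 0.14) were also higher with nitrate. Higher with ammonium were GAT1_2.1 (−3.05 ± 0.28 for nitrate minus ammonium, 8.27-fold), AT2G33710 (−2.67 ± 0.17), AR781 (−2.28 ± 0.26), AT5G05600 (−1.98 ± 0.17), AT1G25400 (−1.92 ± 0.17) and OCT1 (−1.90 ± 0.22). Limma's adjusted p was at most 2.4e-05 among these 12, and the other probe set of GAT1_2.1 gave −1.81.

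PGD3 (1.39 ± 0.07) and PGD1 (1.03 ± 0.06) were higher with nitrate than with ammonium (2 of 2 measured, also when adjusted over the list alone). HHO3 (−0.05 ± 0.12) and HHO2 (−0.23 ± 0.10) were not called. The nitrate response regulators shifted toward nitrate (median 0.0916 and mean 1.36, adjusted p = 1.1e-10 in fry), with 2 of 4 higher, also when adjusted over the list alone. HHO1 made up most of that mean, and its level with ammonium was not shown to be above background. Camera, which compares the list with the other genes, did not call it (adjusted p = 0.09). The loci known to be induced by nitrate had 9 of 11 higher with nitrate (median 1.4, adjusted p = 4.4e-10, and adjusted p = 0.0034 with an estimated correlation), PGM by 1.79 ± 0.09. The oxidative and mitochondrial stress list was lower with nitrate in 4 of 5 members (4 when adjusted over the list alone, adjusted p = 3.4e-06, and adjusted p = 0.021 with an estimated correlation), led by GSTU25 (−1.04 ± 0.13) and STZ (−1.28 ± 0.29). Mitochondrial dysfunction genes, 3 of which are in that list too, were lower with nitrate in 5 of 7, among them AT2G32020 (−1.76 ± 0.17), AT5G14730 (−1.65 ± 0.11) and AT2G41730 (−1.32 ± 0.26), with adjusted p = 4.8e-05 and adjusted p = 0.11 with an estimated correlation. SDH1-2 (0.89 ± 0.08) and IDH-VI (0.35 ± 0.06) were among 3 of 14 tricarboxylic acid cycle and citrate genes higher with nitrate (adjusted p = 0.0013, and adjusted p = 0.38 with an estimated correlation). The median of these 14 genes was 0.0287. GSTU22 was lower by −1.43 ± 0.11 and GSTU21 higher by 0.96 ± 0.15. WRKY53 was lower with nitrate (−0.86 ± 0.11), as was the glutaredoxin gene GRX480 (−1.86 ± 0.26), whereas AT3G62930 was higher (1.88 ± 0.17) and the NRT1/PTR family gene AT1G59740 was higher (0.92 ± 0.12). Core hypoxia genes had 1 of 27 higher and 3 lower with nitrate, and the list was not called (adjusted p = 0.36). UGT76D1 was lower by −1.33 ± 0.11 and UGT72E2 higher by 0.62 ± 0.07.

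Limma called 2430 probe sets between the ions at 1.5 h (1275 higher and 1155 lower with nitrate, and 1114 higher and 1285 lower after samples were centred on their medians), of which 283 differed at least 2-fold (139 higher, 144 lower). Among probe sets without a listed gene, 259681_at (3.85 ± 0.26) and 260624_at (3.55 ± 0.17) were higher with nitrate and 254215_at (−3.40 ± 0.20) and 248164_at (−2.88 ± 0.19) lower.

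At 8 h, among named genes, HHO1 was higher with nitrate than with ammonium by 5.08 ± 0.10 log2, again over a level with ammonium not shown to be above background, and AT5G01740 by 4.58 ± 0.13 (23.9-fold). AT3G46880 (3.79 ± 0.18), AT5G10210 (3.53 ± 0.20), AT5G26200 (3.51 ± 0.30) and AT5G52790 (3.27 ± 0.14) were higher too. OCT1 was lower with nitrate by −4.33 ± 0.22, AT5G38910 by −3.91 ± 0.36, NRT2.5 by −3.60 ± 0.16 (12.2-fold), AT2G33710 by −3.24 ± 0.17, GSTU22 by −2.85 ± 0.11 and SUFE2 by −2.77 ± 0.18. The highest adjusted p of these 12 in limma was 1.7e-06.

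HHO3 was higher with nitrate by 0.81 ± 0.12 and HHO2 by 0.35 ± 0.10. They and HHO1 were 3 of the 4 nitrate response regulators measured (3 when adjusted over the list alone, adjusted p = 2.5e-11 upward, and adjusted p = 0.0061 with an estimated correlation). PGD3 (1.18 ± 0.07) and PGD1 (1.03 ± 0.06) were higher with nitrate (2 of 2, also when adjusted over the list alone), as were all 11 loci known to be induced by nitrate (median 1.50, adjusted p = 2.2e-10, and adjusted p = 0.0014 with an estimated correlation). SDH1-2 (1.46 ± 0.08) and IDH-VI (0.48 ± 0.06) were the 2 of 14 tricarboxylic acid cycle and citrate genes higher with nitrate (adjusted p = 7.8e-06, and adjusted p = 0.15 with an estimated correlation). The median of these 14 genes was 0.0858. Of 11 NRT1/PTR family transporters 3 were higher, AT1G59740 (0.90 ± 0.12), AT1G33440 (0.56 ± 0.11) and the glucosinolate transporter gene GTR2 (0.36 ± 0.07), with adjusted p = 0.00039 and adjusted p = 0.13 with an estimated correlation. Among 28 genes of cell wall loosening 11 were higher and 2 lower with nitrate (adjusted p = 0.0062, and adjusted p = 0.29 with an estimated correlation), with EXPB3 at 0.61 ± 0.12 and EXLB1 at −1.44 ± 0.14. The oxidative and mitochondrial stress list was lower with nitrate (fry, adjusted p = 0.00037) in 2 of 5 members, also when adjusted over the list alone. They were GSTU25 (−1.03 ± 0.13) and NDB2, an alternative NADH dehydrogenase (−0.69 ± 0.10). Camera did not call the list (adjusted p = 0.25). Glutathione S-transferases had 3 of 14 lower and 1 higher (median −0.0195, adjusted p = 3.6e-05 downward, and adjusted p = 0.38 with an estimated correlation). AT3G13610 of the iron deficiency list, an enzyme of coumarin synthesis, was lower by −0.65 ± 0.08 (1 of 2 called, and 2 when adjusted over the list alone). AT4G33040 (−1.70 ± 0.11) and AT5G11930 (−1.39 ± 0.10) were lower and AT3G62930 higher (1.39 ± 0.17) with nitrate. Core hypoxia genes had 1 of 27 higher and 4 lower with nitrate (12 called when adjusted over the list alone, median −0.872), and the list was not called (fry, adjusted p = 0.16).

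Limma called 2430 probe sets between the ions at 8 h as well (1228 higher and 1202 lower with nitrate, and 1349 higher and 960 lower after centring), of which 371 differed at least 2-fold (185 higher, 186 lower). The call of HHO2 was lost without nitrate replicate 1 or 2 (adjusted p = 0.17 and 0.11), without ammonium replicate 1, 2 or 3 (adjusted p = 0.08, 0.083 and 0.14) and with only these 6 samples in the fit (adjusted p = 0.074). Among probe sets without a listed gene, 259681_at (5.02 ± 0.26) and 258629_at (4.11 ± 0.16) were higher with nitrate and 254215_at (−3.90 ± 0.20) and 260540_at (−3.47 ± 0.11) lower.

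A further comparison set 8 h against 1.5 h within each ion. With nitrate, NRT2.5 (−5.51 ± 0.16 log2, 45.4-fold lower), AT5G04120 (−4.81 ± 0.49) and OCT1 (−3.39 ± 0.22) fell, while PDF2.1 (3.25 ± 0.17), COR27 (2.90 ± 0.13) and AT5G14650 (2.39 ± 0.17) rose. HHO1 fell by 0.58 ± 0.10. With ammonium, AT5G04120 (−2.78 ± 0.49), AT5G15950 (−2.18 ± 0.12) and NRT2.5 (−1.83 ± 0.16) fell, while PDF2.1 (4.28 ± 0.17), COR27 (2.67 ± 0.13) and AT1G17615 (1.81 ± 0.11) rose. Limma called 2697 probe sets with nitrate (1322 higher, 1375 lower, 237 at least 2-fold) and 2606 with ammonium (1324 higher, 1282 lower, 186 at least 2-fold). With samples centred on their medians, the higher share was 53.9% in place of 49% of the nitrate calls and 39.7% in place of 50.8% of the ammonium calls.

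The test of whether the ion difference itself changed between 1.5 h and 8 h called 1023 probe sets in limma (519 higher, 504 lower, 191 by at least 2-fold). NRT2.5 had a negative change of the ion difference, of −3.67 ± 0.23 log2 (adjusted p = 3.1e-07), from 0.07 at 1.5 h to −3.60 at 8 h. AT5G38910 (−3.24 ± 0.51) and AT3G28510 (−3.09 ± 0.47) changed downward too, while AT1G49500 (2.72 ± 0.18), AR781 (2.53 ± 0.36) and AT4G27654 (2.5 ± 0.66, adjusted p = 0.042) changed upward. The call of AT4G27654 was lost without nitrate 1.5 h replicate 1, 2 or 3 (adjusted p = 0.084, 0.076 and 0.078), ammonium 1.5 h replicate 1 or 2 (adjusted p = 0.09 and 0.096), nitrate 8 h replicate 2 (adjusted p = 0.07) or ammonium 8 h replicate 1, 2 or 3 (adjusted p = 0.086, 0.063 and 0.088). It was also lost after a second quantile normalization, with only these 4 groups in the fit and with a variance trend and robust estimation (adjusted p = 0.054, 0.058 and 0.11). For HHO1 the change was −0.42 ± 0.15 (adjusted p = 0.13). Nitrate response regulators (median 0.224, 2 of 4 called, 3 when adjusted over the list alone) shifted upward in fry at adjusted p = 0.028, and camera did not call them (adjusted p = 0.69). The fry call was lost without nitrate 1.5 h replicate 1 or 3 (adjusted p = 0.059 and 0.061) and without ammonium 1.5 h replicate 1 or 3 (adjusted p = 0.053 and 0.06). Genes of tetrapyrrole and siroheme synthesis, the cofactor pathway of nitrite and sulfite reductases, had 0 of 12 called and a median of 0.183 (adjusted p = 0.0013, and adjusted p = 0.28 with an estimated correlation). With array weights 1607 probe sets were called, and with samples centred on their medians 64% of the calls were higher in place of 50.7%.

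The responses to the 2 ions overlapped. At 1.5 h, 1498 probe sets were called in the same direction with both ions against the roots before supply (669 higher, 829 lower), among them those of AT2G48080, HHO2, HHO3, PGD1 and PGD3, and 69 in opposite directions. Independent lists of these sizes would share 81.1 higher and 129.8 lower, and unchanged simulated groups set against the same controls shared 0. The first number leaves out the shared controls and the second any response, so neither gives the overlap without a shared response. Log2 changes correlated at r = 0.614 across probe sets, which are not independent replicates, against 0.496 in the simulation, and their covariance was 0.0579 against 0.00668 (difference 0.0512). At 8 h, 2483 were called in the same direction (1022 higher, 1461 lower), among them NRT2.5, AT1G64590 and AT2G40250, and 108 in opposite directions. Independent lists would share 156.7 higher and 263.3 lower, the simulation 0, with r = 0.653 against 0.496 and a covariance of 0.0827 against 0.00668 (difference 0.076). Both ions were compared with the same 3 control samples, which cannot be divided into sets of 2, so part of the excess may come from the shared controls. Changes with time since the harvest before supply were also common to both ions, and they cannot be told apart from a shared response to supply. With array weights the overlap was 3128 at 1.5 h and 3991 at 8 h.

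Calls against the roots before supply that also passed the direct test between ions in the matching direction were counted next. They include genes that responded to both ions by different amounts, such as PGD1, PGD3 and NRT2.5. For nitrate they were 1126 of 3017 at 1.5 h (37.3%, 695 higher and 431 lower), including HHO1, PGD1, PGD3 and SDH1-2, and 1450 of 4689 at 8 h (30.9%, 807 higher and 643 lower), including NRT2.5, OCT1 and GSTU22. For ammonium they were 864 of 3139 at 1.5 h (27.5%, 505 higher and 359 lower), including GAT1_2.1, STZ and AT2G32020, and 756 of 4008 at 8 h (18.9%, 463 higher and 293 lower), including GAT1_2.1. Array weights moved 3 of these 4 counts by over 1.5 times, to 1693 for nitrate and 1539 for ammonium at 1.5 h and to 1223 for ammonium at 8 h. Across times, 2049 probe sets were called in the same direction at 1.5 h and 8 h of nitrate (71 in opposite directions) and 1777 with ammonium (39 in opposite directions), and 977 differed between the ions in the same direction at both times (73 in opposite directions).

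Markers of time of day and of handling had few measured members. GI, a clock gene that peaks near dusk and the 1 measured of its list, rose by 0.39 ± 0.08 at 1.5 h and 0.26 ± 0.08 at 8 h of nitrate and by 0.52 ± 0.08 at 8 h of ammonium. It was at 0.20 ± 0.08 at 1.5 h of ammonium (adjusted p = 0.12) and was not called between the ions at either time (0.20 and −0.25, adjusted p = 0.14 and 0.051). With 1 member, adjustment over the list alone is no adjustment, and limma's unadjusted p was below 0.05 in each of these comparisons (1 of 1). The call at 8 h of nitrate was lost without replicate 2 or 3 of the roots before supply (adjusted p = 0.06 and 0.1), without nitrate replicate 1, 2 or 3 (0.056, 0.055 and 0.081) and with only these 6 samples in the fit (0.057). Its ion difference changed by −0.45 ± 0.11 from 1.5 h to 8 h (adjusted p = 0.031), a value singled out after it was seen. That call was lost without nitrate 1.5 h replicate 2 or 3 (0.076 and 0.069), ammonium 1.5 h replicate 1 (0.083), nitrate 8 h replicate 1, 2 or 3 (0.058, 0.07 and 0.052) or ammonium 8 h replicate 1 or 3 (0.052 and 0.079).

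Of the 2 members of the touch and handling list, 1 was higher at 1.5 h of nitrate, CML38 (2.27 ± 0.66), both at 1.5 h of ammonium, and 1 each at 8 h of nitrate, STZ (0.97 ± 0.29), and at 8 h of ammonium, CML38 (2.44 ± 0.66). Adjusted over the list alone these counts were 2, 2, 1 and 1. Between ions, STZ was the 1 lower with nitrate at 1.5 h (1 when adjusted over the list alone) and none was called at 8 h in either adjustment. The call of CML38 at 1.5 h of nitrate was lost without replicate 1 or 3 of the roots before supply (adjusted p = 0.098 and 0.11), without nitrate replicate 1 or 2 (0.087 and 0.17), with a variance trend and robust estimation (0.1) and with only these 6 samples in the fit (0.064). That of STZ at 8 h of nitrate was lost without replicate 2 or 3 of the roots before supply (0.1 and 0.064), without nitrate replicate 1 (0.1), and under the same 2 settings (0.078 and 0.11). That of CML38 at 8 h of ammonium was lost without replicate 1 or 3 of the roots before supply (0.057 and 0.068), without ammonium replicate 2 or 3 (0.076 and 0.068) and with a variance trend and robust estimation (0.061). The ion difference of STZ changed by 1.88 ± 0.42 from 1.5 h to 8 h (adjusted p = 0.016), also singled out after it was seen, and this call was lost with a variance trend and robust estimation (0.056).

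Members of other short lists moved as follows. NRT2.5 and NRT1.4 fell at 1.5 h of nitrate (−0.54 ± 0.16 and −0.51 ± 0.14, 2 of 2 also when adjusted over the list alone), and NRT2.5 fell at 1.5 h of ammonium (−0.61 ± 0.16, 1 of 2, and 2 when adjusted over the list alone). The call of NRT2.5 was lost at 1.5 h of nitrate without replicate 1, 2 or 3 of the roots before supply (adjusted p = 0.072, 0.072 and 0.079) or nitrate replicate 1 or 2 (0.09 and 0.12), and at 1.5 h of ammonium without ammonium replicate 3 (0.052). That of NRT1.4 was lost without replicate 2 or 3 of the roots before supply (0.059 and 0.076), nitrate replicate 2 or 3 (0.13 and 0.068) and with only these 6 samples in the fit (0.07). COR47 also rose at 1.5 h of ammonium (0.72 ± 0.08), 8 h of nitrate (0.44 ± 0.08) and 8 h of ammonium (0.40 ± 0.08), each the 1 called of 2 (1 when adjusted over the list alone). BHLH101 fell by 0.51 ± 0.12 at 1.5 h and 0.74 ± 0.12 at 8 h of ammonium, where AT3G13610 rose by 0.53 ± 0.08 (1 and 2 of 2 called, also when adjusted over the list alone). RR16, a cytokinin response regulator, rose by 0.41 ± 0.09 at 8 h of nitrate and was higher with nitrate than with ammonium at 8 h by 0.40 ± 0.09 (1 of 2 in both, also when adjusted over the list alone). The latter call was lost without nitrate replicate 2 or ammonium replicate 1 (0.062 and 0.052). The lists for low pH, for sulfate starvation and for organic acids had 1 measured member each, with no call in the 6 comparisons. When adjusted over the list alone, the low pH gene was called at 8 h of nitrate and of ammonium (1 and 1), the organic acid gene at 1.5 h of nitrate (1), and 1 of 2 iron deficiency genes between ions at 1.5 h. For the low pH and organic acid genes, each the 1 measured of its list, this was the unadjusted p.

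Markers of other cell types and states had few measured members. The shoot photosynthesis list had 2, of which neither was called in 5 of the 6 comparisons and LHCB4.1 rose at 8 h of ammonium (0.34 ± 0.11, adjusted p = 0.044). When adjusted over the list alone, 1 was called at 1.5 h of nitrate and 1 at 8 h of ammonium. That call was lost without replicate 2 or 3 of the roots before supply (adjusted p = 0.15 and 0.078), without ammonium replicate 1 or 3 (adjusted p = 0.15 and 0.13), after a second quantile normalization (0.054), after centring (0.059) and with only these 6 samples in the fit (0.057). The mitotic marker AUR1 had changes of −0.11, −0.11, −0.06 and −0.07 log2 against the roots before supply and was not called. Of the 2 root hair markers measured, EXPA18 rose at 1.5 h and 8 h of nitrate (0.41 ± 0.10 and 0.47 ± 0.10) and at 8 h of ammonium (0.44 ± 0.10), and EXPA7 at 8 h of nitrate (0.38 ± 0.12), while neither was called at 1.5 h of ammonium. Both were higher with nitrate than with ammonium at 1.5 h, EXPA18 by 0.41 ± 0.10 and EXPA7 by 0.41 ± 0.12, and neither at 8 h. The counts of 1, 0, 2, 1, 2 and 0 over the 6 comparisons became 2, 0, 2, 1, 2 and 1 when adjusted over the list alone. The call of EXPA18 at 1.5 h of nitrate was lost without replicate 2 or 3 of the roots before supply (adjusted p = 0.058 and 0.06) or nitrate replicate 1 or 3 (0.075 and 0.051). That of EXPA7 at 8 h of nitrate was lost without replicate 2 or 3 of the roots before supply (0.081 and 0.09) or nitrate replicate 2 or 3 (0.089 and 0.098). Between ions at 1.5 h, the call of EXPA18 was lost without nitrate replicate 1 or 3 or ammonium replicate 2 or 3 (0.08, 0.059, 0.05 and 0.074). That of EXPA7 was lost without the same replicates (0.14, 0.087, 0.083 and 0.15), after centring (0.064) and with only these 6 samples in the fit (0.077).

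The 4 fixed lists large enough to test gave 15 calls in 28 tests (5 with an estimated correlation), and the lists of autophagy and of flavonoid and anthocyanin synthesis held 1 of them. That was a fall of the autophagy list at 1.5 h of nitrate (median −0.145, 1 of 7 called, 2 when adjusted over the list alone, adjusted p = 0.029, and adjusted p = 0.69 with an estimated correlation). It was lost without replicate 2 or 3 of the roots before supply (adjusted p = 0.067 and 0.11), without nitrate replicate 1 or 2 (adjusted p = 0.08 and 0.066) and with only these 6 samples in the fit (0.051).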

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

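The splits of the samples for the change of the ion difference, the overlap, the calls that also differed between the ions and the gene lists, and the tests of hypoxia genes and of time, were chosen only after the results were seen.

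A difference between the groups drew attention to 1023 probe sets in which the nitrate against ammonium difference changed between 1.5 h and 8 h by limma's test of that change. NRT2.5 had a fall of this difference (−3.67 log2), with means of 11.62 before supply, 11.08 and 11.01 at 1.5 h of nitrate and ammonium, and 5.57 and 9.18 at 8 h. AT5G38910 changed by −3.24, with means of 8.05 and 8.72 at 1.5 h and 6.25 and 10.16 at 8 h. AT3G28510 changed by −3.09, with means of 6.65 and 5.10 at 1.5 h and 5.09 and 6.62 at 8 h. Upward changes were those of AT1G49500 (2.72, means 8.26 and 7.89, then 9.88 and 6.80), AR781 (2.53, means 5.63 and 7.91, then 6.45 and 6.21) and AT4G27654 (2.5, means 3.43 and 4.29, then 5.09 and 3.45). The call of AT4G27654 ended under each of 9 samples left out that are named with its result, at adjusted p between 0.063 and 0.096. Of 100 splits of the samples within each time, 1, the real one, gave as many as 1023 probe sets, and the highest other gave 824. These splits break up the ion difference itself, so they show that the samples of the ions differed. They cannot exclude chance for a change of that difference with time.

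The splits for the 8 comparisons of 2 groups were too few for a share under 0.05, with 10 each. The real split was the only 1 with as many calls in each. Each other split mixes the 2 groups and so moves their difference into the spread of the fit. Its low count is therefore no measure of the calls that chance gives. The real counts and the highest other were 3017 and 0 for nitrate at 1.5 h, 3139 and 1 for ammonium at 1.5 h, 4689 and 0 for nitrate at 8 h, 4008 and 0 for ammonium at 8 h, 2430 and 1 between ions at 1.5 h, 2430 and 0 between ions at 8 h, 2697 and 0 for nitrate over time and 2606 and 1 for ammonium over time.

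For the overlap at 1.5 h, 1 of 100 drawn splits of the 9 samples, the real one, reached 1498 (highest other 1116), and at 8 h 1 reached 2483 (highest other 2081). The other splits mix groups that differed in many probe sets. The result therefore shows that the groups differed, and it does not test whether the overlap exceeds what shared controls and time give. In the nitrate calls that also differed between the ions, 1 of 100 splits reached 1126 at 1.5 h (highest other 1116) and 4 reached 1450 at 8 h (highest other 2081). Among such ammonium calls, 5 of 100 reached 864 at 1.5 h (highest other 1116) and 11 reached 756 at 8 h (highest other 2081), under a count that sets the real split with its own naming against each other split with the naming of its 3 groups that gave the highest value. That count is not like for like. With a single naming for every split, 1 reached 1126 and 2 reached 1450 for nitrate, and 2 reached 864 and 4 reached 756 for ammonium. At 8 h, 1 of those counted for each ion was the real grouping with its groups renamed. Since these splits mix the groups as well, whether chance is excluded for the nitrate and ammonium calls stays open. Under other namings of the 3 groups the overlap and these calls are the same quantity, so they are not separate tests. For the fixed gene lists, 1 of 100 splits of the 15 samples, the real one, gave 15 calls (highest other 4). These splits mix all groups, so they show that the groups differed and do not test single lists or set them against other genes.

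Core hypoxia genes varied between replicates of a group, with deviations of 0.30, 0.78 and −0.77 log2 in the samples at 1.5 h of nitrate. The members' deviations from their group means correlated at 0.54 on average, against a 95th percentile of 0.04 in 1000 random lists of that size. A list mean spreads this far only where its members vary together, and the test was chosen after that spread was seen. It shows that the members varied together, and it cannot tell whether a factor that differed between single samples was the cause. The ion supplied stays open: ammonium samples lay 0.63 log2 above nitrate samples within times (exact permutation test, two-sided, p = 0.09, n = 6 per ion, 400 permutations). Oxygen in the culture was not stated and not tested.

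Loci known to be induced by nitrate rose with ammonium as well, with a median of 0.952 log2 at 1.5 h. If nitrate carried into the ammonium supply had raised all such genes in proportion, most probe sets at least 4-fold higher with nitrate would be called higher with ammonium. Of 86 such probe sets 75 were (87.2%), a value between the bounds of 50% and 90% set in advance. That share counts only the direction of calls against the same controls, which any shared response also gives, so it cannot test proportion. HHO2 and HHO3 rose at least as much with ammonium as with nitrate at 1.5 h, whereas PGD1 and PGD3 rose less with ammonium. These genes of the list did not rise in one proportion, and carried nitrate otherwise stays open. HHO1 was at 0.00 ± 0.10 log2 with ammonium and 5.50 ± 0.10 with nitrate, from a level not shown to be above background, which as a single gene excludes nothing. Time since the first harvest cannot be told apart from supply for these loci, since no root without supply was sampled at 1.5 h, and a response to nitrogen in either form stays open.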

How the results depend on the processing

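Added after the data were seen were the hypoxia covariate, replicate 1 of the roots before supply left out of every comparison, and the separate table for added lists. Signal over background was not available, so the limit it sets is unknown.

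Counts of calls stayed within 1.5 times in 129 of 146 alternative values and those of at least 2-fold in 137 of 146, counts of the overlap and of calls that also differed between the ions in 91 of 102. With array weights the calls numbered 6061 and 6151 at 1.5 h of nitrate and ammonium against the roots before supply, 7177 and 6631 at 8 h and 1607 for the change of the ion difference, the overlap 3128 and 3991, and calls that also differed between the ions 1693 for nitrate and 1539 for ammonium at 1.5 h and 1223 for ammonium at 8 h. The cause was not tested. With only probe sets of 1 gene, where fewer were tested, the 9 comparisons gave 1503, 1581, 2360, 2020, 1203, 1190, 1382, 1265 and 483 calls, the overlap was 733 and 1242 and such calls were 546, 423, 706 and 361. At 1.5 h of ammonium only the groups compared, with fewer samples, gave 2069 and the hypoxia covariate 1149. That covariate gave 2083 at 8 h of ammonium. The covariate itself differed between the ammonium groups and the roots before supply, so these counts cannot show how many calls went with the hypoxia genes. Camera called 5 of 28 tests of fixed lists in place of 15, and 6 of 140 of added lists in place of 51. Leaving out single replicates gave no count beyond 1.5 times. Without replicate 1 of the roots before supply, counts rose also in comparisons that do not use it but share the estimate of spread. They were 2856 and 2850 in place of 2430 and 2430 between ions at 1.5 h and 8 h. Over time they were 3126 in place of 2697 with nitrate and 3185 in place of 2606 with ammonium. For the change of the ion difference 1440 were called in place of 1023. After centring on medians the calls for ammonium over time were 979 higher and 1485 lower in place of 1324 and 1282, those for the change of the ion difference 673 and 378 in place of 519 and 504, and 51.9% in place of 43.3% of the calls at 1.5 h of ammonium were higher. Of the calls between ions 46.4% in place of 52.5% were higher at 1.5 h and 58.4% in place of 50.5% at 8 h, and over time with nitrate 53.9% in place of 49%. The replicate numbers were not taken as pairs over all groups, since only 14 of 30 same-number pairs had residual correlations over 0.1 (−0.162 to 0.369, median 0.092, other pairs −0.047) and 8 of 15 samples correlated best with their own number. All 3 pairs of the roots before supply and at 1.5 h of ammonium (0.3, 0.101 and 0.185) and 8 of 10 pairs of replicate 1 were over 0.1, so sharing within a number stays open. The block gave 3302, 3482, 5071, 4457, 2754, 2674, 2989, 3042 and 1180 calls. It ended those of AT2G32020 at 1.5 h of nitrate and between ions at 8 h (adjusted p = 0.052 and 0.055), of HTB4 between ions at 1.5 h (0.054), of oxidative and mitochondrial stress at 1.5 h of nitrate and for the change of the ion difference (0.061 and 0.077), of SWEET genes between ions at 8 h (0.056) and of NRT1/PTR genes for the change of the ion difference (0.076). It gained those of HTB11 at 1.5 h of nitrate, LHCB4.1 at 8 h of nitrate, NDB2 at 8 h of ammonium and CHLI2 and petG between ions at 8 h, and changed no other call of a named gene or list.

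Named genes kept direction and call in 6235 values, lost the call in 387, gained it in 52 and turned direction in 22. The 22 were of genes not called. With array weights ARR15 at 1.5 h of ammonium was −0.02, BGLU28 at 8 h of nitrate −0.01 and WRKY53 at 8 h of ammonium 0.02. Between ions at 8 h AT1G51340 was 0.02 after centring and cICDH −0.01 after quantile normalization. Without single replicates BGLU28 ranged from −0.10 to 0.05 at 1.5 h of nitrate, −0.01 to 0.06 at 8 h of nitrate, −0.01 to 0.12 at 8 h of ammonium and −0.08 to 0.05 between ions at 8 h. ARR15 at 1.5 h of ammonium ranged from −0.01 to 0.27, RR16 at 8 h of ammonium from −0.04 to 0.08, and AUR1 between ions at 8 h from −0.01 to 0.03. WRKY53 ranged from −0.16 to 0.03 at 8 h of nitrate, −0.10 to 0.08 at 8 h of ammonium and −0.14 to 0.02 between ions at 8 h. Between ions, AT1G51340 ranged from −0.03 to 0.18 at 1.5 h and −0.16 to 0.09 at 8 h, and AT3G10040 from −0.91 to 0.39 at 1.5 h.

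Lists were unmoved in 1407 values, lost the call in 187, gained it in 63 and turned the direction of the test in 25, here with medians. Flavonoid genes were 0.13 and 0.0168 with array weights at 8 h of nitrate and ammonium, and without single replicates −0.122 to 0.109 at 1.5 h of nitrate, −0.174 to 0.0554 and −0.215 to 0.0832 at 8 h, −0.205 to −0.0728 between ions at 1.5 h and 0.0891 to 0.214 for the change of the ion difference. SWEET genes were −0.0986 with array weights and −0.0882 to 0.0021 without single replicates at 1.5 h of nitrate, 0.0633 with camera and 0.0278 to 0.108 without single replicates at 8 h of nitrate, and 0.00304 without dim probe sets between ions at 1.5 h. Glutaredoxins were 0.0669 without dim probe sets at 1.5 h of ammonium and 0.0561 with camera at 8 h of nitrate. Between ions at 8 h they were 0.126 after centring, 0.0982 with camera and 0.0679 to 0.145 without single replicates, and for the change of the ion difference 0.218 after quantile normalization, 0.0278 without dim probe sets (adjusted p = 0.033, and 0.87 before) and 0.138 to 0.271 without single replicates. Glutathione S-transferases were 0.0394 with camera between ions at 1.5 h, and autophagy genes 0.0144 with array weights and −0.00429 to 0.0793 without single replicates between ions at 8 h. The cause was not tested. Among 61 tests of added lists never called under any setting, 121 of 975 values turned direction, in 35 tests. They are kept apart by a choice made after those numbers were seen.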

Other observations

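The comparison of the time courses of the ions was chosen only after the results were seen.

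Of 47 UDP-glycosyltransferases, 3 rose and 11 fell at 8 h of nitrate, and 8 rose and 7 fell at 1.5 h of ammonium (mixed fry test, adjusted p = 2.3e-12 and 3.1e-13), and the other members were not called. The mixed test passed in 110 of 140 tests of added lists, against 51 for the test in one direction and 6 with an estimated correlation, and in 14 of 28 tests of fixed lists. UGT73D1 was lower with nitrate than with ammonium at 8 h by −1.6 ± 0.17 log2 and UGT87A2 by −0.95 ± 0.10. Of 40 class III peroxidases, enzymes of the cell wall, 8 rose and 9 fell at 8 h of ammonium (adjusted p = 3.3e-16 in the mixed test), with AT5G19890 at 0.96 ± 0.14, and 7 rose and 5 fell at 8 h of nitrate (9e-16). Auxin genes had 6 of 18 higher at 8 h of ammonium (adjusted p = 0.012, and adjusted p = 0.35 with an estimated correlation), with GH3.3 at 0.65 ± 0.15, PUCHI at 0.55 ± 0.12 and LBD16 at 0.42 ± 0.09 log2. The upward call ended without replicate 3 of the roots before supply (adjusted p = 0.054).

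The list of oxidative and mitochondrial stress was also tested against the roots before supply at the other times. It had 1 of 5 lower at 1.5 h of nitrate (1 when adjusted over the list alone, adjusted p = 0.036 downward, and adjusted p = 0.78 with an estimated correlation). At 8 h of nitrate 1 was higher and 2 lower (3 when adjusted over the list alone, adjusted p = 0.028 downward, and adjusted p = 0.78 with an estimated correlation), and at 8 h of ammonium none was called in either adjustment (adjusted p = 0.028 upward, and adjusted p = 0.45 with an estimated correlation). The call at 1.5 h of nitrate ended without replicate 1 or 2 of the roots before supply (adjusted p = 0.082 and 0.11) and without nitrate replicate 1 or 2 (0.15 and 0.063). It also ended with array weights (0.15), with the replicate number as a block (0.061) and with only these 6 samples in the fit (0.22). That at 8 h of nitrate ended without replicate 1 or 2 of the roots before supply (0.073 and 0.067) and nitrate replicate 1 or 3 (0.087 and 0.16), and with array weights (0.14). That at 8 h of ammonium ended without replicate 3 of the roots before supply (0.084) and ammonium replicate 2 or 3 (0.056 and 0.11), and with only these 6 samples in the fit (0.14). Flavonoid and anthocyanin genes had 0 of 3 called in each main comparison, and when adjusted over the list alone 1 at 8 h of nitrate and 0 in the others. Photosynthesis genes encoded in the nucleus had at most 3 of 17 higher and 1 lower, and 69 genes encoded in the plastid had medians between −0.0977 and 0.0529 log2 with no call of the list in the main comparisons.

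The changes from 1.5 h to 8 h with nitrate and with ammonium, which share no samples, had 918 probe sets called in the same direction (440 higher, 478 lower) and 103 in opposite directions, against 154.4 expected of independent lists. That number leaves out the estimate of spread that both comparisons share in the same fit, so it does not give the overlap without a shared change. Log2 changes of both comparisons correlated at r = 0.429 across probe sets, which are not independent replicates. PDF2.1 and COR27 rose and NRT2.5 and AT5G04120 fell in both.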
